A study of Mus musculus with 12 samples.

How the data were processed

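RNA-seq was done on BV2 cells, a mouse microglial cell line, given extracellular vesicles (EVs) from other BV2 cultures for 24 h. The 12 libraries form 4 groups of 3, named by the treatment of the cells that gave the vesicles: control_EV, LPS_EV, TGFB_EV and IL10_EV. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates are separate cultures, and the design text speaks of individual wells, so p-values measure only the spread between these samples, which may be technical.

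Per the labels' protocols, RNA was column-purified, cDNA was made with SMART-Seq v4, libraries were made with Nextera XT after 18 PCR cycles, and paired reads of 150 nt were planned. These kits do not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The authors deposited whole-number counts per Ensembl mouse gene ID, not normalised, in 4 tables of 6 columns. A pair of the tables was identical, so 3 were used, and the control_EV columns were the same in all of them. Per the submitters' processing notes DESeq2 was used; the aligner, the counting program, the genome build and the annotation are not given in the sources used here. Each table holds 57010 rows, of which 52029 were matched to a gene symbol through a table of Ensembl IDs; rows without a symbol held 1.81% of the counts. Library totals lay between 10497757 and 13647007 counts, so that 3 counts correspond to between 0.220 and 0.286 CPM, the count scaled to a common library total. Reads carry no molecular identifiers, so such floors cover counting error only.

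Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr with a minimum count of 10, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). Each comparison with control_EV used its own 6 libraries without covariates. Pairs of treatments were compared in a fit of all 12 libraries. Fold changes are log2 values with their standard error (SE), and levels are TMM-scaled CPM, given as mean ± SD. Gene lists, 19 for processes and cell states and 6 for markers of other cells, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 where at least 3 members were measured, with Benjamini-Hochberg adjustment over the lists. On counts simulated from the real means and library sizes, with 100 rows changed for each fold size, the edgeR test recovered 61% of 1.5-fold and 78% of 2-fold changes for LPS_EV (10523 rows, 10 false calls among 167). For TGFB_EV it recovered 52% and 70% (10524 rows, 8 false among 138), and for IL10_EV 44% and 73% (10613 rows, 11 false among 133).

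The lists, the tests and the rule for named rows were chosen before the data were examined. The rule took called rows with a gene name (no Gm number, Rik, LOC or bare Ensembl symbol), a mean of at least 5 CPM and all 3 treated values on 1 side of all 3 control values, and named the 12 largest rises and 12 largest falls. Where fewer than 10 passed, rows with the smallest p were added up to 10 and are given as values only. Cytokine and receptor rows (Tlr4, Cd14, Tgfb1, Tgfbr1, Tgfbr2, Il10, Il10ra, Tnf, Il1b, Il6) were to be given always, up to 4 members from each list described, and 6 rows per pair of treatments.

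Because the levels of many rows did not go with their labels, a check of row identity was added after the data were examined. The exons of each row, placed with GENCODE M21, were moved along the chromosome by a displacement that was constant over stretches of neighbouring rows. The displacements were fitted without the group labels, in steps of 100 bp, by rewarding rows with many counts that met exons of 501 widely expressed genes and penalising rows with counts that met no exon, with a penalty of 15 for each change of displacement. The search reached 1000 kb to either side, and 1900 kb below and 500 kb above on chromosome X; these ranges and the scores were also set after the data were examined. A stretch was counted as supported where its score lay at least 5 above the best displacement more than 100 steps away. Support therefore does not fix a position more finely than that. Supported displacements reached down to 1.3 kb, and the support of such small ones did not weigh them against no displacement. A protein-coding gene was taken as met by a row when its exons and the moved exons shared any step of 100 bp. An overlap of 300 bp was required only of the widely expressed genes in the fit and of ribosomal protein genes in the check given below. A gene met may therefore rest on a short overlap. In simulated data with known displacements, 99.8% and 99.5% of rows on the 2 chromosomes tried were placed within 300 bp. There the displacement changed once per chromosome, counts were drawn as the score assumes, and rows that met no exon had no counts. The real fit had 87 stretches on 20 chromosomes, and some rows with counts met no exon. The simulated shares therefore do not measure accuracy on the real counts. These matches are estimates: no coordinates are given, none were converted between builds, and a row may still hold reads of several genes.

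DESeq2 1.42.0 was run as another tool. Further alternatives were DESeq2 size factors, no filter, a filter of 10 CPM in 3 libraries, the replicate number as a block, a fit of all 12 libraries, a 1.5-fold threshold and leaving out each library. Added after the data were examined were robust dispersion, counts summed by the gene met at the displaced position, and some lists and correlations without IL10_EV replicate 2. In these sums a row that met several genes gave all its counts to the gene with the largest overlap. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.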

Results

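BV2 mouse microglial cells were profiled after 24 h with EVs, membrane particles that cells release, to ask how vesicles from microglia in different states alter gene expression in recipient microglia. The vesicles came from BV2 cells that were untreated or had been given LPS, a bacterial activator of Toll-like receptor 4, or the cytokines TGF-β or IL-10. Each of the 4 groups had 3 libraries. Library totals averaged 11504880 ± 873367 counts in control_EV, 11141800 ± 428695 in LPS_EV, 11837832 ± 652369 in TGFB_EV and 13403334 ± 232764 in IL10_EV (SD, n = 3). An exact two-sided permutation test against control_EV gave p = 0.6, 0.7 and 0.1, where 0.1 is the smallest p that 3 against 3 allows.

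Gene labels and levels did not go together in these tables. Rows labelled Eef1a1 and Tmsb4x (a translation factor and an actin-binding peptide, abundant in most cells), Ftl1, Ctsd, Trem2, Tnf and Cd14 had 0 counts in all 12 libraries, and the row labelled Actb had 4.01 CPM. The 82 rows labelled with ribosomal protein genes had a median of 0.111 CPM; 53 lay under 1 CPM, 19 had no counts and 4 reached 100 CPM. The 37 mitochondrial rows had 0 counts, and the displacements given below were not fitted to them. The highest level, 23992 CPM, was in the row labelled Cyth2, and 67 of 1969 rows labelled as olfactory or vomeronasal receptors, genes of sensory neurons, reached 5 CPM. When exons were displaced along the chromosomes, 73 of 87 stretches, holding 95.0% of the rows with a position, had a supported displacement with a median size of 138 kb. In a fit that did not reward ribosomal protein genes, the 28 rows whose displaced exons met them had a median of 1397 CPM. That fit still spared rows with counts that met these exons from its penalty, so the check is not independent of it. After displacement 93.1% of rows of at least 5 CPM met a protein-coding exon, a share that the fit itself favours, and 14.7% of them still met the gene of their label. Rows are therefore named below by their label, "the row labelled X", with the gene its displaced exons met given as an estimate; background on function is for the gene met.

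**Figure D1:**
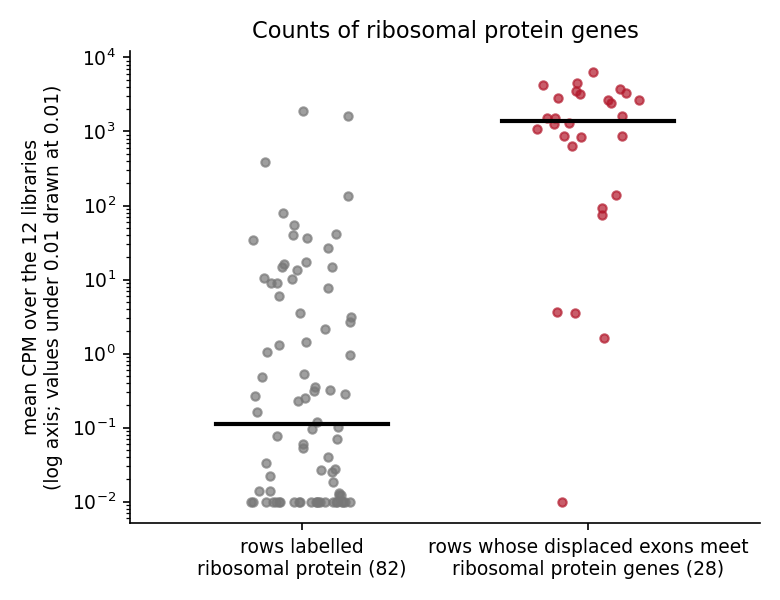
Mean CPM over the 12 libraries (log axis) for 82 rows labelled with ribosomal protein genes and for 28 rows whose displaced exons met ribosomal protein genes. The displacements came from a fit that did not reward these genes. Each point is a row and each line a median. The medians are 0.111 and 1397 CPM.

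LPS_EV was compared with control_EV to ask what vesicles of LPS-treated microglia change in recipient cells. No group was given LPS or a cytokine without vesicles. In each comparison, agent carried over with the vesicles therefore cannot be told apart from an effect of the vesicles themselves. The edgeR test with Benjamini-Hochberg adjustment called 86 of 10523 rows, 57 higher and 29 lower. Of these, 50 met only genes other than that of their label, and 26 still met their own gene. The largest named rise was in the row labelled Clec4e (ENSMUSG00000030142), which met Clec4d, a C-type lectin receptor of myeloid cells. It rose from 3.12 ± 0.34 to 7.97 ± 3.06 CPM (log2 fold change 1.35, SE 0.27, adjusted p = 0.0105). The row labelled Ksr1 met Nos2, the inducible nitric oxide synthase, and rose by 0.96 on the log2 scale (adjusted p = 0.00858). The row labelled H2al1o met Cybb, the catalytic subunit of the phagocyte NADPH oxidase, and rose from 91.6 ± 14.7 to 146 ± 20.2 CPM (log2 fold change 0.67, adjusted p = 0.000255).

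Further rises in LPS_EV were found in rows that met genes of several kinds. The row labelled Csrnp2 met Slc11a2, an iron transporter, with a log2 fold change of 0.94, and that labelled Vmn2r19 met both its own gene and Clec4e, another C-type lectin receptor, with 0.95. The rows labelled Npl, Denr, Cgn and Arfgef3 met Dhx9, Abcb9, Selenbp2 and a stretch with Nhsl1, Hebp2 and Arfgef3, with log2 fold changes of 0.94, 0.77, 0.72 and 0.67. Rows labelled Bend6, Prex1 and Slc12a1 met no protein-coding exon and rose by 0.79, 0.73 and 0.70. The change with the smallest p was in a row that the naming rule leaves out, chosen here after its values were seen. Labelled LOC102637012, it met Saa3, an acute-phase protein, and Saal1, and lay at 598 ± 310 CPM in LPS_EV and 156 ± 37.2 in control_EV (log2 fold change 1.94, SE 0.23, adjusted p = 7.5e-05).

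Rows that fell in LPS_EV included the row labelled Frmpd1 (ENSMUSG00000035615), which met its own gene, with a log2 fold change of -1.29 (SE 0.26, adjusted p = 0.00972). Rows labelled Alox12 and Rnasek both met Mgl2, a galactose-type lectin of macrophages, with log2 fold changes of -1.01 and -0.96. The row labelled Cd72 met its own gene, an inhibitory receptor best known from B cells, and fell from 183 ± 11.3 to 135 ± 22.5 CPM (log2 fold change -0.43). Smaller falls were in rows labelled Serpinb1a (met Serpinb9b, -0.55), Spag1 (Spag1 and Polr2k, -0.53), Dnah7c (Dnah7c and Slc39a10, -0.47) and Mei1 (Desi1 and Pmm1, -0.44). Rows labelled Slc25a16 (met Ccar1), Atp6v1e2 (Mcfd2), Pip4k2a (its own gene) and Olfr923 (Vwa5a) had log2 fold changes of -0.40, -0.37, -0.34 and -0.33. Among the cytokine and receptor rows, that labelled Tlr4 met its own gene and lay at 21.2 ± 3.01 CPM against 24.8 ± 2.79 (adjusted p = 0.531). Tgfbr1, which also met its own gene, had a log2 fold change of -0.10 (adjusted p = 0.537). The rows labelled Il1b, Il6 and Tgfb1 met Slc20a1, Hadhb and Lipe, and none was called; those labelled Cd14, Tgfbr2, Il10, Il10ra and Tnf had too few counts to be tested in any comparison with control_EV.

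The LPS_EV count depended on single libraries: it was 53 without control_EV replicate 1, 27 without LPS_EV replicate 2 and 18 without LPS_EV replicate 3. It was 0 when the spread was estimated over all 12 libraries, and DESeq2 called 119 rows, 42 higher and 77 lower.

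**Figure D2:**
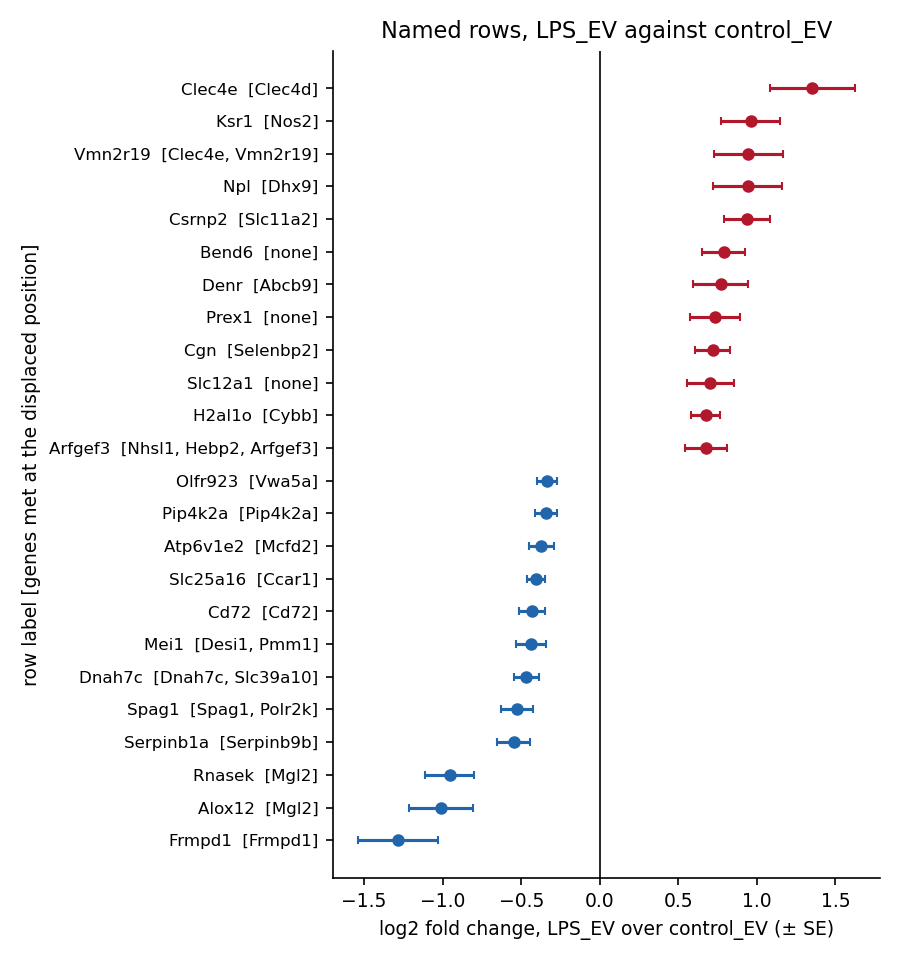
Log2 fold changes (points, with bars of 1 SE) of the 24 named rows in LPS_EV over control_EV, from the edgeR fit with 3 libraries per group; labels give the row label and, in brackets, the genes met by its displaced exons. The row labelled Clec4e lies highest at 1.35 and that labelled Frmpd1 lowest at -1.29.

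Gene lists were tested on the rows as labelled, whose membership is subject to the displacement. Most rows of at least 5 CPM did not meet the gene of their label. A list that did not pass therefore says little about the genes it names. For LPS_EV none of 20 lists passed, with adjusted p between 0.106 and 0.969; with an estimated correlation the lowest adjusted p was 0.848. The lowest was for antigen presentation, whose 3 measured members had a median log2 fold change of 0.40 and of which 0 were called over all rows or adjusted over the list alone. Among 13 measured inflammatory and NF-kB labels, Birc3 was called (log2 fold change 0.31, adjusted p = 0.0258), and adjusted over the list alone 2 were called; the Birc3 row met Tmem123. Of 6 alternative activation labels, the row labelled Mrc1, which met its own gene, the macrophage mannose receptor, and that labelled Klf4, which met no protein-coding exon, fell by 0.30 and 0.27 on the log2 scale; adjusted over the list alone 2 fell and 1 rose. Of the NRF2 labels Slc7a11, a cystine transporter that met its own gene, rose by 0.50, the only one of 9 both over all rows and adjusted over the list alone. Among markers of other cells, the row labelled Rbfox3, a gene of neurons, rose by 0.67 on the log2 scale; it met Lgals3bp, an interferon-induced secreted protein.

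TGFB_EV was compared with control_EV in the same way. The edgeR test called 4 of 10524 rows, all lower, and 656 had an unadjusted p under 0.05. Unchanged rows would reach that limit in a share of 0.05, and this share was somewhat higher. The row labelled Pno1 met Ppp3r1, a calcineurin regulatory subunit, and fell from 8.61 ± 1.98 to 1.87 ± 0.589 CPM (log2 fold change -2.19, SE 0.28, adjusted p = 0.00952). The row labelled Pck1 met Rae1, an mRNA export factor, and had a log2 fold change of -0.97 (adjusted p = 0.0270). The other called rows lie outside the naming rule and were chosen after their values were seen. Gm17112, which met Actl6b, lay at 49.0 ± 3.63 CPM against 84.8 ± 7.92 (adjusted p = 0.0051), and ENSMUSG00000120226, which had no position, had a log2 fold change of -0.63. Rows with the next smallest p were those labelled Tagap (met Gm49673 and Rnaset2a), Socs7 (Npepps), Slc25a29 (Yy1), Tada3 (Camk1) and Lmnb2 (Ap3d1). Their log2 values were -1.69, -1.04, -0.99, -0.96 and -0.74, and none was called. The rows labelled Scx (met Cyc1), Tnnt2 (Phlda3 and Tnni1) and Mboat7 (no supported match) had -0.72, -0.47 and -0.44, also not called. The labels Tgfbr1 and Tlr4, which met their own genes, had log2 fold changes of 0.00 and -0.15 (adjusted p = 0.995 and 0.857). None of 20 lists passed in camera on the rows as labelled (adjusted p 0.762 to 0.971), under the limit given for the LPS_EV lists. Lists by the gene met are given further below. Without TGFB_EV replicate 3, 419 rows were called, 107 higher and 312 lower; without TGFB_EV replicate 1 or control_EV replicate 1 there were 0, without control_EV replicate 3 there was 1, and without TGFB_EV replicate 2 or control_EV replicate 2 there were 2. Replicate 3 differed from replicates 1 and 2 with a chi-square per degree of freedom of 10.01 and 16.9, where replicates 1 and 2 gave 4.41. Its Pearson r was 0.9929, 0.9938 and 0.9929 with the control_EV libraries and 0.9903 and 0.9865 with TGFB_EV replicates 1 and 2, so it lay nearer to control_EV than to its own group. DESeq2 called 17 rows, and the edgeR fit of all 12 libraries called 0.

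IL10_EV was compared with control_EV in the same way. The edgeR test called 0 of 10613 rows, and DESeq2 called 1. In edgeR 334 rows had an unadjusted p under 0.05, less than the share of 0.05 that unchanged rows would give. The rows with the smallest p included those labelled Rnasek and Alox12, which met Mgl2, with log2 values of -0.97 and -0.82 (SE 0.18 and 0.24, adjusted p = 0.9996). Frmpd1 and Cd72, which met their own genes, had -1.04 and -0.34, and the row labelled Tfcp2, which met Slc11a2 and Gm5475, had 0.31. The rows labelled Tlr4 and Tgfbr1 had -0.09 and -0.08 (adjusted p = 0.9996). The remaining rows were those labelled Dstyk (met Tmcc2, -0.54), Rsph3a (Fgfr1op, 0.53), Mlc1 (Pim3, -0.42), Dpy30 (Birc6, 0.37) and Raph1 (its own gene, -0.29). None of 20 lists passed in camera on the rows as labelled (lowest adjusted p = 0.996), again under that limit. The count was 1 without IL10_EV replicate 1 and 2 without IL10_EV replicate 2.

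Libraries of the IL10_EV group differed among themselves. Replicate 2 differed from replicates 1 and 3 with a chi-square per degree of freedom of 18.7 and 24.8, while replicates 1 and 3 gave 5.92. Each library was placed along the LPS_EV difference by regressing its deviation from control_EV on the LPS_EV effect over called rows, with the library itself kept out of that effect. IL10_EV replicate 2 showed a share of 1.29, with 98.8% of the 86 rows on the LPS_EV side. Replicates 1 and 3 showed 0.219 and 0.320. Shares in LPS_EV were 0.407, 1.04 and 0.951 for replicates 1, 2 and 3, over 127, 27 and 18 rows called without each. In control_EV they were -0.0648, 0.373 and 0.247, over 53, 102 and 65 rows called without each. Over the 127 rows called without LPS_EV replicate 1, IL10_EV replicates 1, 2 and 3 had 0.197, 0.914 and 0.349. The matched Saa3 sum lay at 276, 1126 and 454 CPM in IL10_EV replicates 1, 2 and 3, and Nos2 at 12.1, 61.5 and 10.7.

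**Figure D3:**
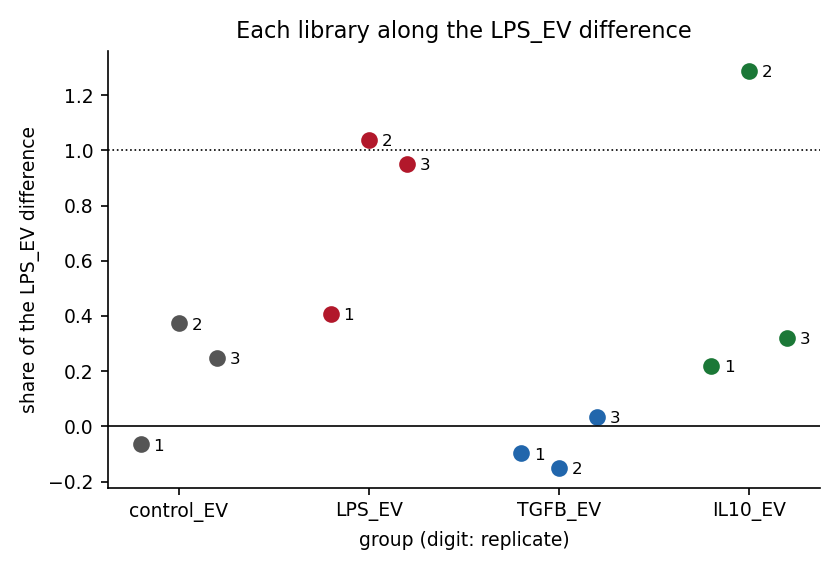
Share of the LPS_EV difference (y axis, no unit; 0 is the control_EV level and 1 the LPS_EV mean) in each of the 12 libraries, by group, with replicate numbers beside the points. The rows used differ between libraries. IL10_EV replicate 2 lies at 1.29 and LPS_EV replicate 1 at 0.407, next to control_EV replicate 2 at 0.373.

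The treatments were compared with each other in the fit of all 12 libraries, over 11267 rows. For LPS_EV against TGFB_EV edgeR called 0 rows; 1442 had an unadjusted p under 0.05, and DESeq2 called 93. The smallest p values were for rows labelled Pno1 (met Ppp3r1, log2 difference 2.39), Mllt1 (met C3, the central complement component, 0.69) and Serpinb1a (met Serpinb9b, -0.73), all with an adjusted p of 0.0585. The rows labelled Iqsec3 (met Iqsec3 and Slc6a12), Dmxl2 (its own gene) and Denr (Abcb9) followed with 0.56, 0.85 and 0.94 (adjusted p = 0.0734). Fitted on the 6 libraries alone, edgeR called 120 rows, 87 higher in LPS_EV, and without TGFB_EV replicate 3 the fit of the remaining libraries called 134; without LPS_EV replicate 1 it called 4. For LPS_EV against IL10_EV edgeR called 0 rows, and DESeq2 called 1. In edgeR 634 rows had an unadjusted p under 0.05, close to the share of 0.05 that unchanged rows would give. The row labelled Ceacam19, which met Relb, an NF-kB subunit, had a log2 difference of 0.67 (adjusted p = 0.0944). Rows labelled Ackr2 (met Nktr), Cntnap1 (Naglu and Hsd17b1), Hoxd3os1 (no protein-coding exon) and Rfx3 (its own gene) had 0.61, 0.26, 3.45 and 2.49 (adjusted p = 0.794). The rows labelled Hoxd3os1 and Rfx3 had means of 0.916 and 1.31 CPM in LPS_EV and of 0.0760 and 0.225 in IL10_EV, near the level of 3 counts, where a fitted difference depends on the model. Without IL10_EV replicate 2 the count was 3. For TGFB_EV against IL10_EV edgeR called 0 rows, with 842 at an unadjusted p under 0.05 and 9 by DESeq2. The rows labelled Rnf219 (met no protein-coding exon), Iqsec3, Rnf216 (no supported match), Flnc (its own gene), Fgfr1op (no protein-coding exon) and Ttc9c (Taf6l and Polr2g) had log2 differences of 0.48, -0.52, 2.68, 0.32, -1.17 and -0.38, with adjusted p from 0.162 to 0.272. The row labelled Rnf216 had means of 1.97 CPM in TGFB_EV and 0.298 in IL10_EV, near the same level. Without IL10_EV replicate 1 the count was 1.

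Fold changes of the comparisons were correlated across 7499 rows, which are not independent replicates. The comparisons share their controls, so unchanged groups with shared controls were simulated in 20 draws. The control libraries were simulated as well, so the simulated values do not carry deviations particular to the real control_EV libraries. Each row was drawn independently, without differences between libraries that many rows share. The spread of the simulated values may therefore be too narrow to judge a departure from them. LPS_EV and TGFB_EV fold changes had a Pearson r of 0.160, where simulation gave 0.501, and a covariance of 0.00453 against 0.0113. LPS_EV and IL10_EV had an r of 0.540 against 0.505 and a covariance of 0.0131 against 0.0113; without IL10_EV replicate 2 the r was 0.266. TGFB_EV and IL10_EV had an r of 0.373 against 0.503 and a covariance of 0.00932 against 0.0112; without IL10_EV replicate 2 the r was 0.5845. No called row was shared between comparisons, where independent lists of the observed sizes would share 0.0113 lower rows for LPS_EV and TGFB_EV. With disjoint controls, 2 for 1 comparison and 1 for the other, the mean r was -0.102 for LPS_EV and TGFB_EV (-0.207 to -0.0289), 0.133 for LPS_EV and IL10_EV (0.102 to 0.151) and 0.0265 for TGFB_EV and IL10_EV (-0.105 to 0.107), so part of each correlation may come from the shared controls. A set of 1 control adds noise, which also lowers r.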

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

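Robust dispersion, sums by the gene met, and lists and correlations without IL10_EV replicate 2 were chosen after the data were seen; the other alternatives were planned. The LPS_EV count of 86 stayed within 1.5 times with DESeq2 size factors (84), DESeq2 (119), a strict filter (85), robust dispersion (83), sums by gene met (81) and rows that met another gene (59). It was 165 without a filter, 24 above 1.5-fold, 55 over rows that met 1 gene only and 0 in the fit of all 12 libraries; leaving out 1 library gave 18 to 127, and 14 to 119 by gene met (49 without control_EV replicate 1, 30 without LPS_EV replicate 2). The TGFB_EV count of 4 became 17 with DESeq2, 111 without a filter, 1 with a strict filter, 0 in the fit of all 12, 9 with robust dispersion, 1 by gene met and 2 over rows that met 1 gene or another gene; leaving out 1 library gave 0 to 419, and 0 to 378 by gene met. The IL10_EV count of 0 became 1 with DESeq2 and 22 without a filter; leaving out 1 library gave 0 to 2, and 0 to 1 by gene met. For LPS_EV against TGFB_EV the count of 0 became 120 on 6 libraries, 93 with DESeq2 and 340 without a filter, with 0 to 134 on leaving out 1 library. For LPS_EV against IL10_EV it became 1 with DESeq2 and 18 without a filter, with 0 to 3. For TGFB_EV against IL10_EV it became 9 and 160, with 0 to 1. Removing rows or libraries changes the number of tests and the spread; beyond that the cause was not tested.

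With the replicate number as a block the counts were 209 for LPS_EV, 3 for TGFB_EV, 3 for IL10_EV, 2 for LPS_EV against TGFB_EV and 0 for the other pairs. Whether the numbers pair the samples is not settled by these values. Same-numbered deviations of LPS_EV and control_EV correlated only at 0.102, 0.0419 and 0.0253, although each of these 3 LPS_EV libraries correlated best with its own number. Those of TGFB_EV and control_EV correlated at -0.0361, -0.145 and -0.247. For IL10_EV and control_EV they were -0.0147, 0.226 and 0.254, with replicates 2 and 3 best with their own number and replicate 1 not. Lists as labelled gave 0 calls with the preset and the estimated correlation and with the block. By gene met, LPS_EV lists numbered 6 (5 over rows that met 1 gene only, 7 with the block, 0 with an estimated correlation, 4 to 7 on leaving out 1 library). For TGFB_EV they numbered 1 (0, 0, 0, and 0 to 4) and for IL10_EV 2 (3, 2, 0, and 0 to 5).

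With disjoint controls the correlation of LPS_EV and TGFB_EV fold changes was -0.102, that of LPS_EV and IL10_EV 0.133 and that of TGFB_EV and IL10_EV 0.0265; without IL10_EV replicate 2 the correlations with IL10_EV gave 0.266 and 0.5845. Of 164 values of named LPS_EV rows under other settings 118 kept their call and 46 lost it, among them 24 in the fit of all 12 libraries and 15 with DESeq2; on leaving out 1 library 92 of 144 kept it. For the named TGFB_EV falls 10 of 13 and 4 of 12 kept it. Direction turned only in rows that were not called, on leaving out 1 library: for TGFB_EV Il1b (log2 values from -0.013 to 0.26), Tgfb1 (-0.32 to 0.089), Il6 (-0.14 to 0.23) and Tgfbr1 (-0.017 to 0.036), and for IL10_EV Tlr4 (-0.17 to 0.017), Il6 (-0.32 to 0.053) and Il1b (-0.18 to 0.19); the cause was not tested. Pseudocount alternatives apply to normalised values and were not run. Totals of 10497757 to 13647007 counts limit what can be seen in rows near 0.220 to 0.286 CPM.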

Other observations

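All tests in this part, by gene met at the displaced position, of explanations and of splits of the libraries, were chosen only after the results were seen. Counts summed by the gene met gave 81 of 5883 genes called for LPS_EV against control_EV, 57 higher and 24 lower. A row that met several genes counted only for that with the largest overlap, so sums may hold reads of other genes or miss a gene. The row labelled Cyth2 (23992 CPM), for example, met Gys1, Bax and Ftl1 and counted for Gys1. The list of inflammatory and NF-kB genes rose (camera adjusted p = 0.00043, 16 genes, median log2 fold change 0.24; adjusted p = 0.313 with an estimated correlation). Of its members 6 rose over all genes and 7 adjusted over the list alone. They included Saa3, an acute-phase protein (663 ± 342 against 172 ± 40.4 CPM, n = 3), Acod1, which makes itaconate (log2 fold change 0.94), Il1a, an interleukin-1 cytokine (0.94), and Nos2 (0.97). The interferon list rose as well (adjusted p = 0.000762, 20 genes, of which 17 had positive values; adjusted p = 0.404 with an estimated correlation), with 4 members called over all genes and 4 adjusted over the list alone, Oasl2, Oas3, Oas2 and Lgals3bp (log2 fold changes 0.61, 0.50, 0.55 and 0.68). NRF2 targets rose (adjusted p = 0.00628, 10 genes; adjusted p = 0.443 with an estimated correlation), with 2 called and 5 adjusted over the list alone, among them Slc7a11 (0.51) and Gstm1, a glutathione transferase (0.25). Alternative activation genes fell (adjusted p = 0.0207, 7 genes; adjusted p = 0.313 with an estimated correlation), with 2 called and 4 adjusted over the list alone, led by Mgl2 (-0.98) and Mrc1 (-0.28). Cell cycle genes rose (adjusted p = 0.0127, 17 genes, 0 called by edgeR and 3 adjusted over the list alone; adjusted p = 0.313 with an estimated correlation). Genes of the unfolded protein and integrated stress response fell (adjusted p = 0.00297, 18 genes, median -0.09; adjusted p = 0.359 with an estimated correlation), although the called member, Slc7a11, rose; adjusted over the list alone 1 rose and 2 fell. Without LPS_EV replicate 2 or 3 or control_EV replicate 2 the number of lists was 4, 5 and 4.

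By gene met, TGFB_EV differed from control_EV in 1 of 5887 genes and IL10_EV in 0 of 5921 in edgeR (DESeq2 was run on labelled rows only). For IL10_EV 179 genes had an unadjusted p under 0.05, less than the share of 0.05 that unchanged genes would give. Glycolysis and hypoxia genes fell in TGFB_EV as a list (adjusted p = 0.0330, 14 genes, 0 called, 0 adjusted over the list alone; adjusted p = 0.675 with an estimated correlation), with a median log2 fold change of -0.19. Without TGFB_EV replicate 3 the list passed at 0.000808, with 7 members called lower and 11 adjusted over the list alone (adjusted p = 0.508 with an estimated correlation). In IL10_EV the interferon list rose (adjusted p = 0.0304, 20 genes; adjusted p = 0.638 with an estimated correlation), and so did the cell cycle list (adjusted p = 0.00542, 17 genes; adjusted p = 0.638 with an estimated correlation); both had 0 members called over all genes or adjusted over the list alone. Without IL10_EV replicate 2 neither passed (adjusted p = 0.532 and 0.196), and glycolysis genes fell (adjusted p = 0.000798, 13 genes, 0 called over all genes, 8 lower adjusted over the list alone; adjusted p = 0.689 with an estimated correlation).

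The levels of many rows did not go with their labels, and 3 explanations were tested. A shift of the labels by a fixed number of rows is argued against, since over moves of up to 3000 rows at most 13.4% of ribosomal protein labels fell on rows of at least 100 CPM. For genomic DNA or degraded RNA in place of spliced transcripts, rows were taken whose displaced exons met ribosomal protein genes, in a fit that did not reward these genes. Of them 78.6% reached 100 CPM, against 3.26% of all rows. That fit still spared rows with counts that met these exons from its penalty. The row labelled Caskin1 also met Ndufb10, which stayed among the rewarded genes. The check is thus not independent of the fit and does not exclude this explanation. Positions displaced along the chromosomes, as reads aligned to 1 genome build and counted with gene positions of another could give, remain a candidate explanation. The rows that met ribosomal protein genes had a median of 1397 CPM, under the same limit. The score of the fit was 8715 against at most 970 in 9 permutations of the counts. Permuted counts have lost any link to position, so they do not weigh displaced against undisplaced positions. With no displacement the score was -532, but the fit seeks the highest score and could not end below that value. Which builds were used was not tested, and no biological explanation was tested.

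IL10_EV replicate 2 lay along the LPS_EV difference, with a share of 1.29 where the control_EV libraries had an SD of 0.225. The control_EV shares were taken over other rows, called without each control, so this SD is only a rough yardstick. Replicate 2 was singled out because it stood apart from replicates 1 and 3. Their shares therefore cannot test an effect of IL10_EV vesicles of the same size in every library. Shares differed within LPS_EV as well (0.407, 1.04 and 0.951 in replicates 1, 2 and 3). IL10_EV replicates 1 and 3 reached at most 0.320, below the highest control_EV library at 0.373, a share taken over other rows. A swap with an LPS_EV library stays open: LPS_EV replicate 1 had a share of 0.407, next to that control, and the split of LPS_EV and IL10_EV libraries with most calls exchanges these libraries. Against it, of 127 rows called without LPS_EV replicate 1 that library lay on the LPS_EV side in 89.8% and IL10_EV replicates 1 and 3 in 66.9% and 74.0%, and it correlated at 0.9923 and 0.9931 with the other LPS_EV libraries and at 0.9905 and 0.9894 with those of IL10_EV. These values do not decide it: on those rows the share of LPS_EV replicate 1 lay less than 1 control SD above those of IL10_EV replicates 1 and 3 (0.197 and 0.349), r within groups spanned 0.9818 to 0.9934, the r of LPS_EV replicate 1 with control_EV was 0.9920 to 0.9923, and IL10_EV replicate 2 had an r of 0.9890 to 0.9900 with LPS_EV and of 0.9818 and 0.9854 with its own group. A single wrong label or LPS in that well would give a share such as the 1.29 seen (0.914 over those 127 rows) and cannot be told apart from a swap by it, although replicate 2 lay above every LPS_EV library in the scores of cell cycle genes (0.336 against at most 0.0936) and cholesterol synthesis (0.346 against at most 0.0204). An effect of IL10_EV vesicles that varies between wells was not tested.

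Libraries of the same group differed along a gradient of glycolysis genes by gene met, with scores of 0.06, 0.26 and -0.09 in control_EV, 0.12, 0.01 and 0.10 in LPS_EV, -0.23, -0.41 and 0.15 in TGFB_EV and -0.10, 0.39 and -0.25 in IL10_EV replicates 1, 2 and 3. Over the 12 libraries, with 18 relations and 100000 permutations each, 10 had an adjusted p under 0.05 by r and 6 by rho, so the gradient was not confined to glycolysis. The largest r was with ligands and receptors of the EV cytokines (r = 0.889, permutation p = 0.00012, adjusted 0.00108, and rho = 0.853, permutation p = 0.00084, adjusted 0.00378). The other lists that passed by both were homeostatic microglia genes (r = 0.872), the IL-10 and STAT3 response (0.865), TGF-β and SMAD targets (0.859), cholesterol synthesis (0.843) and the unfolded protein and integrated stress response (-0.837). Without TGFB_EV and IL10_EV replicate 2, the farthest from the median, r for these lists in that order was 0.751, 0.885, 0.724, 0.711, 0.799 and -0.646. Homeostatic microglia genes then had the largest r. Among lists that passed by r only, r went from 0.661 to 0.331 for inflammatory, 0.634 to 0.314 for interferon, 0.650 to 0.367 for disease-associated microglia and -0.662 to -0.408 for immediate early genes. Of the variance of the glycolysis score, 20.6% lay between groups (permutation p = 0.579, where chance gives 27.3%). The gradient was picked because libraries of the same group differed along it, so this share cannot test the kind of vesicle as the whole cause. Sequencing depth is argued against by an r of 0.0020 with library totals (permutation p = 0.995). The rho was -0.0559 (permutation p = 0.869), and r was -0.441 without TGFB_EV and IL10_EV replicate 2. Differences between wells, such as cell density or nutrient use, may lie behind the gradient and were not tested.

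The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. For LPS_EV against control_EV the real split gave 86 calls and the highest other 4 (1 split with as many). For TGFB_EV against control_EV it gave 4 and the highest other 260 (2 splits with as many), which points to a structure of the samples. The split with 260 set TGFB_EV replicates 1 and 2 and control_EV replicate 3 against the rest. For IL10_EV against control_EV all splits gave 0 calls (10 with as many). Splits between treatments were fitted with all 12 libraries, as in the comparisons themselves. For LPS_EV against TGFB_EV all gave 0 calls there (10 with as many). For LPS_EV against IL10_EV the real split gave 0 and the highest other 13 (10 with as many); for TGFB_EV against IL10_EV it gave 0 and the highest other 478 (10 with as many), which again points to a structure of the samples.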
